A study of Caenorhabditis elegans with 2 samples.

How the data were processed

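The samples were 2 biological replicates of transgenic young adult C. elegans hermaphrodites carrying ZNF-207 with a C-terminal GFP-FLAG tag, with sonicated chromatin from whole animals immunoprecipitated with an anti-GFP antibody, per the description in the labels. Another label names B0035.1, the tagged gene, as the antibody, and it was taken here as the target. They form 1 group, and the replicate numbers are those of the labels. The labels name a possible control, which was not used here, so no value is set against a control in these comparisons.

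The deposited files are narrowPeak lists in the ce10 and ce11 builds. For each build there is a list per replicate, a list made from both replicates together and a thresholded list. As the deposited files are labelled, the first 3 hold peaks and background made as input for the irreproducible discovery rate procedure (IDR), which uses how alike peaks rank in replicates to choose the peaks kept, and the last is the optimal IDR-thresholded set. The aligner, the peak caller and their versions are not given in the sources used here. The signal of each peak, in column 7, was made by the authors' peak caller and deposited on a scale set within each list, so signals were ranked within a list and not compared in size between lists, apart from 1 count in the 2 builds and the correlations of the replicates, which do not depend on a scale factor. The deposited −log10 q-value of each peak, in column 9, was at its highest value of 2.47 in all 750 thresholded ce11 peaks, so it could not rank them and was used only to break ties. The deposited offset in column 10 gave each peak's summit. Exact repeats of an interval occurred 12 times in the thresholded ce11 list, where 1 interval carries several summits, and each summit was counted. All 750 thresholded ce11 peaks were the 750 highest by signal of the list made from both replicates. The lists hold no read counts, so the depth of each sample is unknown, and the Wilson intervals at the 95% level cover the counting of peaks only.

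Coordinates were taken from the lists and printed 1-based. The ce11 lists were annotated with the WBcel235 genome, whose chromosomes held all thresholded ce11 summits, and with Ensembl release 115. The ce10 lists were not annotated. For their X share the ce11 chromosome lengths served as the expectation, and for their shifts the farthest peak end was taken as the length of each chromosome. A promoter window ran from 500 bp upstream to 200 bp downstream of the outermost start of a protein-coding gene, and each summit was assigned to 1 location in the order promoter, coding exon, UTR, intron and intergenic, where intergenic means outside protein-coding genes. For noncoding RNA genes a summit within 200 bp of the gene counted, and each class was set against the genes of all other classes judged in the same way. The mitochondrial genome entered the replicate comparison, the locations and the words, and was left out of the chromosome, gene list and divergent promoter tests.

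The replicates were compared by the overlap of their 750 strongest peaks (summits within 200 bp) against 1000 circular shifts along each chromosome, and by correlations with 100000 permutations. The promoter share and the noncoding classes were tested against 1000 shifts of all summits, one-sided. Gene lists, divergent promoters (an opposite start within 1000 bp) and shares between classes of peaks were tested with two-sided Fisher exact tests. The shares of the X chromosome and of the autosome centres were tested with exact binomial tests, and 6-letter words within 50 bp of the summit against a window centred 300 bp to the left with exact McNemar tests. Benjamini-Hochberg adjustment was made over the 36 gene lists, the 2080 words, the 6 chromosomes or the tests of each smaller family, with a threshold of 0.05. The gene lists were also set against the 1000 shifts, one-sided, with the same adjustment. The shifts keep the spacing of peaks but not the base composition or the accessibility of the places they move to. Genes that overlap or share a start region can share a peak.

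The gene lists, 29 of protein-coding genes and 7 of noncoding classes, the tests, the rule for named items and most alternatives were fixed before the data were examined. The rule names the 20 peaks of highest signal, the tagged gene, the 4 members with the strongest peak of each over-represented list, up to 2 members of each other list, all spindle and kinetochore members with a peak, the 5 over-represented words with the lowest p and a fixed list of 10 words. Other items were chosen after their values were seen. The alternatives fixed in advance were the stronger 375 peaks, each replicate alone, the strongest peaks of the pooled list, promoter windows of 200 bp upstream to 100 bp downstream and of 1000 bp upstream to 200 bp downstream, starts of every gene class, only the nearest gene, a background of genes with an unthresholded peak, summit distances of 100 and 500 bp, 375 or 1500 peaks per replicate, the ce10 build, other expected shares, word windows of 25 bp, right flanks, words of 5 and 7 letters, and distances of 10 and 40 kb around the tagged gene. Leaving out mitochondrial peaks, keeping 1 summit per 500 bp, leaving out peaks within 200 bp of a tRNA gene, correlations over the 750 strongest nuclear peaks of 1 replicate, and words on X or the autosomes alone were added after seeing the data. So were the classes of X peaks, the recruitment motif, which was searched within 100 bp of summits with at most 2 mismatches, and the comparisons of words near tRNA genes.

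The procedures for the promoter share, the gene lists, the words and the replicate overlap were tested on simulated data, and the other tests were not. With summits planted in promoters, the share was 38.5% where 39.1% was expected (p = 0.001 by permutation, the smallest possible), and with random summits it was 12.3% (permutation p = 0.775). A planted gene list was called in 20 of 20 draws and 1 of 560 other lists was called. With nothing planted 0 of 2080 words were called on 750 summits, and a planted word took place 1, with 3 words called. Those summits were placed at random. The simulation therefore does not cover words called because real summits and flanks differ in base composition. A planted overlap of 60.0% was found as 60.0%. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.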

Results

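Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed with an anti-GFP antibody on whole Caenorhabditis elegans hermaphrodites that carried ZNF-207 with a C-terminal GFP-FLAG tag. ZNF-207 (gene znf-207, sequence name B0035.1) is a zinc finger protein, and its human counterpart binds microtubules and kinetochore proteins. The animals were young adults collected 50 hours after synchronization as starved L1 larvae. The data comprised 1 group of 2 biological replicates, and no control samples were analysed here. Peak lists were used for each replicate, for both replicates pooled and for a thresholded set, each in the ce10 and the ce11 genome build. In ce11 the thresholded set held 750 peaks, of which 731 lay on the nuclear chromosomes and 19 on the mitochondrial genome. The pooled list and the list of replicate 1 held 30000 peaks each, and that of replicate 2 held 25036. The signal of each peak is the authors' own value. It was used to rank and describe peaks within a list, apart from the correlations of the replicates and 1 count in the 2 builds. The median signal of the thresholded peaks was 114 and the median width 460 bp. The lists give no read counts, so sequencing depth was unknown and the intervals given here cover the counting of peaks only. Coordinates are ce11, and the annotation is that of the WBcel235 assembly.

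The 20 peaks with the highest signal were the first question, because they mark the places of highest signal in the thresholded set. Of these, 17 lay on the mitochondrial genome, with the highest at 4147 to 6463 (signal 6441, summit 4661, in the window of the protein-coding gene WBGene00000829). The strongest nuclear peak lay on chromosome III from 3867339 to 3867765, in the promoter window of rpl-3, which encodes a protein of the large ribosomal subunit (signal 583, summit 293 bp upstream of the start). The next lay on the X chromosome from 11093937 to 11094395 (signal 474), between genes and 1481 bp from the tRNA gene WBGene00014538. The remaining nuclear peak of this group lay on X from 6296329 to 6296821 (signal 457), in an intron of mom-1, a gene of the Wnt secretion pathway. These 3 nuclear peaks were also among the 23 strongest of each replicate. Whether the mitochondrial peaks also occur in untagged animals was not analysed here.

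The replicates were compared to ask whether the same regions were enriched in both. The peak at rpl-3 ranked 18 in replicate 1 and 20 in replicate 2, and the peak at sls-2.1, a spliced leader RNA gene on chromosome II, ranked 25 in both. The promoter peaks of hsp-1, which encodes a constitutive cytosolic chaperone, and of cox-5A, a cytochrome c oxidase subunit, ranked 61 and 58 in replicate 1 and 69 and 51 in replicate 2. Weaker promoter peaks differed more, such as that of mrg-1, a chromodomain protein gene, at rank 2507 in replicate 1 and 310 in replicate 2. Among the 750 strongest peaks of replicate 1, 449 (59.9%, 95% Wilson interval 56.3 to 63.3) had a summit within 200 bp of one among the 750 strongest of replicate 2. After circular shifts of the peaks along each chromosome the mean was 1.54% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Of the thresholded peaks, 84.5% were among the 750 strongest of replicate 1 and 71.5% among those of replicate 2. Across the 737 thresholded peaks found in both replicates, Spearman's rho of the signals was 0.436 and Pearson's r of log10 signal was 0.810 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). These correlations are across peaks, which are not independent replicates, and the thresholded peaks, being the strongest of the pooled list, were chosen by the signal of both replicates together. Among nuclear peaks chosen by 1 replicate, a setting added after seeing the data, rho was 0.564 over the 709 of the 750 strongest of replicate 1 found in replicate 2 and 0.569 over the 714 of the 750 strongest of replicate 2 found in replicate 1 (permutation p = 1e-05 for each, the smallest possible). The Pearson value rested in part on the mitochondrial peaks, as r was 0.545 and rho 0.392 over the 719 nuclear peaks. On X rho was 0.542 over 174 peaks and on the autosomes 0.340 over 545, and this difference was not tested.

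**Figure D1:**
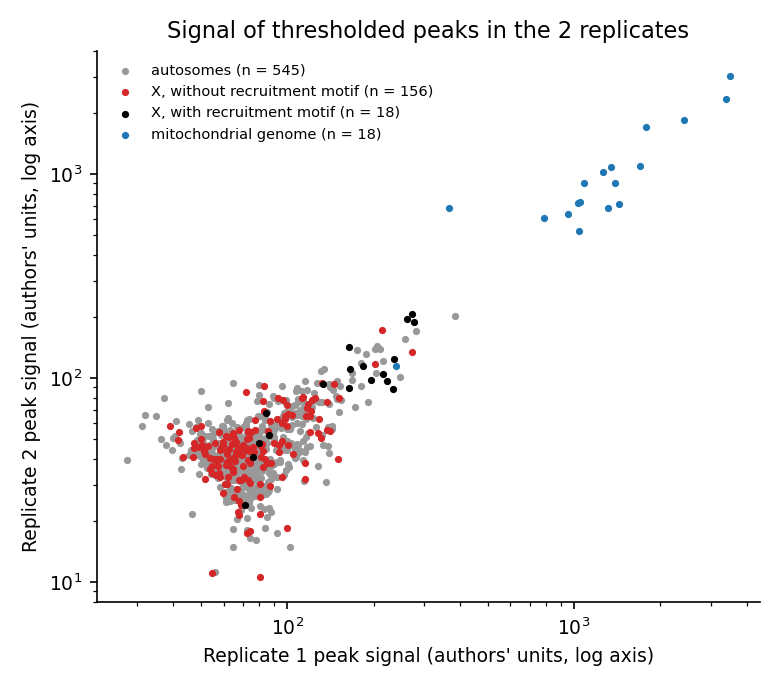
Signal of each thresholded peak in replicate 1 (x axis) and replicate 2 (y axis), both in the authors' units on log axes, with 1 point per peak found in both replicates and colours for autosomal, X and mitochondrial peaks and for X summits with a match to the recruitment motif described with the X chromosome. All but 1 of the mitochondrial points lie above the nuclear ones, and rho over all 737 peaks is 0.436.

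The location of the peaks relative to genes was examined next. Promoter windows, from 500 bp upstream to 200 bp downstream of a protein-coding start, held 278 of the 750 summits (37.1%, 33.7 to 40.6). Strong examples were tasp-1, which encodes a threonine aspartase, with its peak on chromosome III from 10759075 to 10759453 (signal 451), and cdc-48.1, which encodes an AAA ATPase of protein quality control, with its peak on chromosome II from 10563433 to 10563692 (signal 317). Both were chosen after their values were seen. A further 253 summits (33.7%) were intergenic and 146 (19.5%) intronic, while 47 (6.27%) lay in coding exons, 18 in 3′ UTRs and 8 in 5′ UTRs. Shifted summits fell in promoter windows in 13.7% of cases, and none of the 1000 shifts exceeded 17.6% (one-sided permutation p = 0.001, the smallest possible). Coding exons and introns held fewer summits than after shifting, where the means were 21.97% and 31.3% (one-sided permutation p = 0.001 for each, the smallest possible). The intergenic share exceeded its shifted mean of 29.6% (two-sided permutation p = 0.0240). In all, 334 protein-coding genes had a summit in their window, 327 nuclear and 7 mitochondrial. Over the nuclear genes, the strongest summit lay at a median of -193 bp from the start, with an interquartile range of -303.5 to -91.5 bp.

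**Figure D2:**
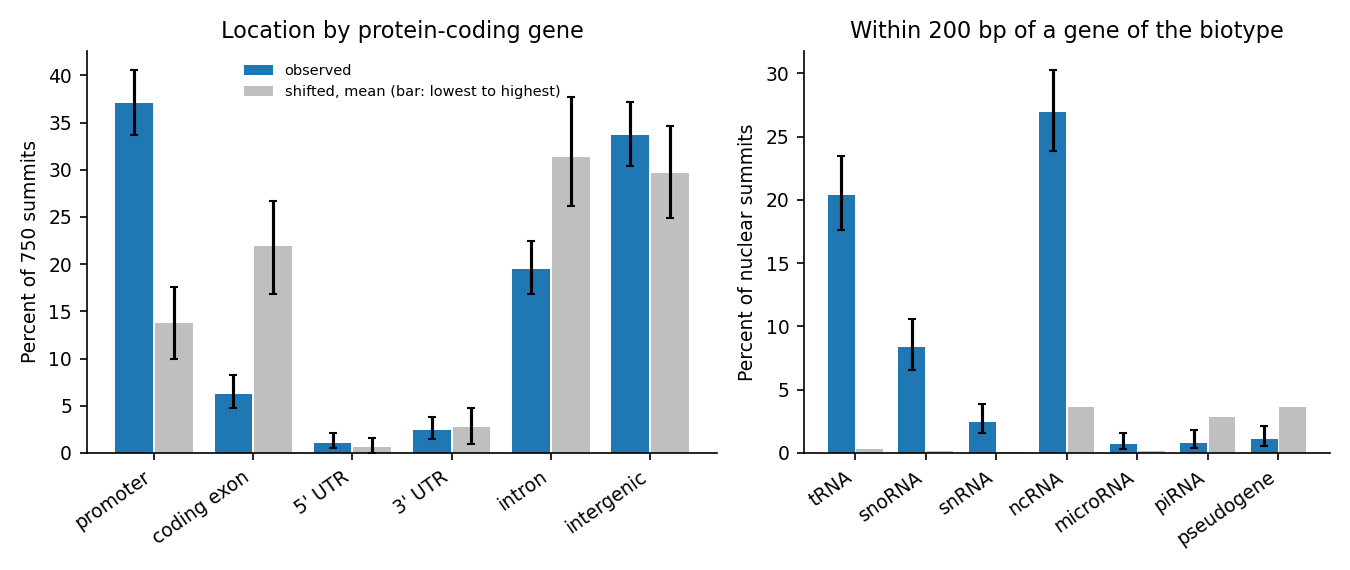
Left, percent of the 750 thresholded summits in each annotated location, and right, percent of the 731 nuclear summits within 200 bp of a gene of each noncoding class, as observed (blue, 95% Wilson intervals) and as the mean over 1000 circular shifts (grey, with the lowest and highest on the left). The promoter share of 37.1% lies above every shift, the coding exon share of 6.27% below every shift, and tRNA genes reach 20.4% against 0.299%.

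Head-to-head gene pairs were common among the genes with a promoter peak. Of the 327 nuclear genes, 134 (40.98%, 35.8 to 46.4) had an oppositely directed protein-coding start within 1000 bp upstream, against 17.3% of the other 19646 genes. Examples are sec-61.B and trap-3 on chromosome IV, which encode a subunit of the protein translocation channel and a protein associated with it and which share 1 summit at 2389141. Another is the pair rpl-12 and lin-54, a ribosomal protein gene and a gene of the DREAM repressor complex, which share the summit at 13240684 on the same chromosome. The odds ratio was 3.31 (2.65 to 4.14, two-sided Fisher exact p = 3.39e-23). The windows of such pairs overlap, so 62 summits fell in the windows of 2 or more genes and 216 in that of 1 gene, and the genes of a pair are not independent. A shared summit counts for both genes, which can raise the odds ratio, and the interval and p do not allow for this. Counting only the nearest gene was not tried for this result.

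Genes of short noncoding RNAs held a large part of the nuclear peaks. Within 200 bp of a tRNA gene lay 149 of the 731 nuclear summits (20.4%, 17.6 to 23.5), against a mean of 2.19 after shifting. Another 61 (8.34%) lay by a snoRNA gene, whose products guide RNA modification, against 1.32, and 18 (2.46%) by an snRNA gene, a class that here includes spliced leader RNAs, against 0.413. Together these classes accounted for 226 summits (30.9%, 27.7 to 34.4), and each class exceeded its shifts at a permutation p of 0.001 (one-sided, the smallest possible). In replicates 1 and 2 taken separately, 18.4% and 16.8% of the 750 strongest nuclear peaks lay by tRNA genes, 8.40% and 7.33% by snoRNA genes and 2.40% and 2.27% by snRNA genes. The broad class of other noncoding RNA genes lay within 200 bp of 197 summits (26.9%) against 26.6 after shifting, and a summit can count under several classes.

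Counted by gene, 170 of 612 tRNA genes had a peak (odds ratio 20.7, 17.2 to 25.1, Fisher exact adjusted p = 6.74e-137). The strongest were by WBGene00014531 and WBGene00014532 on chromosome V (summit 15465194, signal 231) and by WBGene00023110 and WBGene00023111 on X (summit 3036140, signal 228). Among snoRNA genes, 59 of 346 had a peak (odds ratio 9.82, adjusted exact p = 8.71e-34), led by ZK994.7 in an intron of pxn-1 (chromosome V, 8500388 to 8500692, signal 345). C51F7.3 and C51F7.4 followed in an intron of frm-7 (12303427 to 12303756, signal 330), then T03F7.8 (summit 11314212, signal 240). Among snRNA genes, 14 of 129 had a peak (odds ratio 5.58, adjusted exact p = 4.44e-06). The strongest were sls-2.1 (chromosome II, 5844639 to 5845021, signal 410), sls-2.4 (chromosome I, 4171968 to 4172656, signal 345) and sls-2.2 (chromosome II, summit 5543771, signal 290), which encode leader RNAs used in trans-splicing. R07E5.16 on chromosome III followed (summit 10989796, signal 219). MicroRNA genes were not over-represented against other genes (5 of 261, adjusted exact p = 1.00), although 5 nuclear summits lay within 200 bp of one against 0.903 after shifting (one-sided permutation p = 0.00300), the strongest by cel-mir-51 (signal 175) and cel-mir-52 (signal 121), and without replicate 2 there were 8 such genes. None of the 20 nuclear rRNA genes had a peak (adjusted exact p = 1.00). The mitochondrial rRNA genes WBGene00014472 and WBGene00014454, which this test left out, held summits (signals up to 2320 and 2223).

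Genes for germline small RNAs and pseudogenes rarely had peaks. Of 15363 piRNA genes, 6 had a summit within 200 bp (odds ratio 0.0118, adjusted exact p = 1.67e-162), among them 21ur-5229 (signal 137) and 21ur-12279 (signal 122), against a mean of 38.7 after shifting (one-sided permutation p = 0.001, the smallest possible). Without replicate 1 there were 9 (odds ratio 0.0188). These odds ratios, against genes of all other classes, take no account of gene length and treat neighbouring genes as independent. The shifts keep the same genes, so 6 against 38.7 is the closer contrast. Of 2128 pseudogenes, 8 had one (odds ratio 0.164, adjusted exact p = 3.12e-11), among them WBGene00014724 (signal 166) and WBGene00023323 (signal 150), against a shifted mean of 25.3 (permutation p = 0.001, the smallest possible). Some of the named genes share their summit with a gene of another class. The summit by 21ur-5229 was also that of the tRNA gene WBGene00022903, and the summit by 21ur-12279 that of the atp-1 promoter. WBGene00014724 shared its summit with the snoRNA gene D1046.6.

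Of the 29 lists of protein-coding genes, 6 were over-represented among genes with a promoter peak, and these held 48 of the 327 nuclear genes with one. Cytosolic ribosomal protein genes led, with 16 of 83 having a peak. Besides rpl-3 these included rpl-20 (signal 347, 288 bp upstream), rpl-35 (310, 458 bp upstream) and rpl-15 (265, 350 bp upstream), all of the large subunit. The odds ratio was 15.03 (8.62 to 26.2, adjusted exact p = 3.19e-12). The summits of rpl-20, rps-19, rps-20, rps-23 and ubq-2 lay nearer to the start of another protein-coding gene. For rpl-20 this was Y17G9B.5, at 174 bp. Chaperone genes followed with 11 of 68 (odds ratio 11.96, 6.21 to 23.0, adjusted exact p = 7.67e-08). Their strongest members were hsp-1 (226), cct-8 of the cytosolic chaperonin (166), hsp-3 of the endoplasmic reticulum (154) and the co-chaperone gene dnj-9 (154). In the group of chromatin regulators 8 of 58 had a peak (odds ratio 9.83, 4.62 to 20.9, adjusted exact p = 1.89e-05), with lin-54 (175), the histone-binding protein gene lin-53 (161), the retinoblastoma counterpart lin-35 (139) and the histone demethylase gene jmjd-1.2 (125) highest. The peak of lin-54 is the one it shares with rpl-12. Genes of secretion and the endoplasmic reticulum had 7 of 66 (odds ratio 7.26, 3.29 to 16.02, adjusted exact p = 0.000362), and 4 without replicate 1 (odds ratio 4.62, adjusted exact p = 0.0485, range over alternatives 0.000320 to 0.0582). They were led by the exocyst gene sec-15 (223, at a summit beside the tRNA gene WBGene00022947), the channel subunit genes sec-61.G (185) and sec-61.B (171) and trap-3 (171). Genes of 1 list that share a summit, as sec-61.B and trap-3 do, each count. The intervals and p-values of the lists do not allow for this.

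Smaller groups also passed the threshold. Oxidative phosphorylation had 4 of 48 genes (odds ratio 5.52, 1.97 to 15.4, adjusted exact p = 0.0255), namely the cytochrome c oxidase genes cox-5A (247) and cox-5B (193), the ATP synthase gene atp-1 (122) and nduf-11 (99.5). Ubiquitin and E2 enzymes had 3 of 27 (odds ratio 7.57, 2.27 to 25.3, adjusted exact p = 0.0285), namely ubc-6 (136), ubq-2 (98.1), which encodes ubiquitin fused to a ribosomal protein and was also counted among the ribosomal genes, and uba-2 (91.2). The last is on the list as fixed, though it encodes neither ubiquitin nor an E2 enzyme. Over the 9 alternative settings that could change these lists, ribosomal proteins and chromatin regulators passed in all 9, with highest adjusted exact p of 0.0184 and 0.0240. Their odds ratios fell to 5.68 and 4.89 against genes with an unthresholded peak, ribosomal proteins had 4 genes in place of 16 with the narrower promoter window, and chromatin regulators 4 in place of 8 with that window or with only the nearest gene counted. Chaperones and secretion each passed in 8, ending at an adjusted exact p of 0.0582 with that window, and their odds ratios fell to 6.53 and 3.68 against genes with an unthresholded peak, that of chaperones to 5.96 with the narrower window. Oxidative phosphorylation passed in 6 (adjusted exact p from 0.00189 to 0.648) and not without replicate 1 (3 genes, 0.0953). Ubiquitin and E2 enzymes passed in 3 (adjusted exact p from 0.00779 to 1.00) and, with 2 genes each, not without replicate 1 (0.129) or replicate 2 (0.176).

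**Figure D3:**
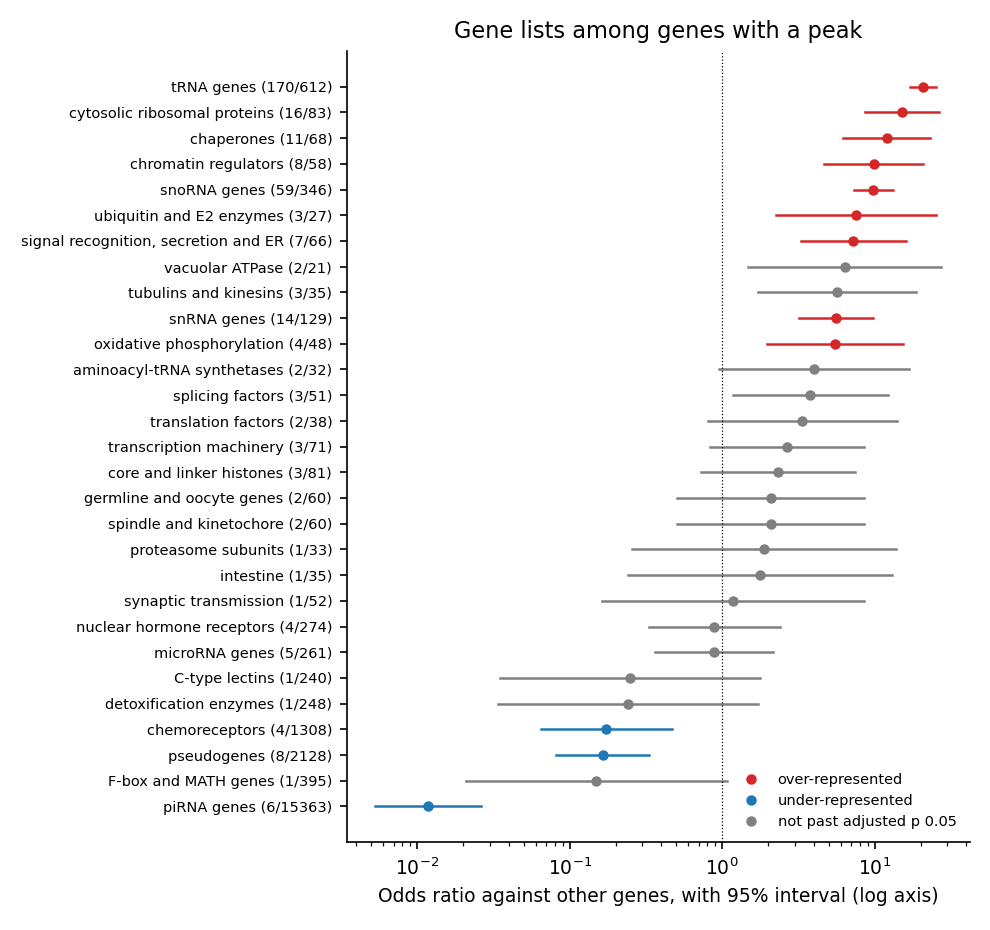
Odds ratio, on a log axis with 95% intervals, for each fixed gene list with at least 1 member holding a peak, where values above 1 mean more peaks than among other genes. Lists without such a member are not drawn; tRNA genes lie highest at 20.7 and piRNA genes lowest at 0.0118.

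Spindle and kinetochore genes, the group nearest to the known partners of the human counterpart, were not over-represented. Of 60 such genes 2 had a promoter peak (odds ratio 2.08, 0.505 to 8.55, adjusted exact p = 0.357). These were knl-3, a kinetochore component on chromosome V (signal 103.8, summit 1868800, 413 bp upstream), and mdf-1, a spindle checkpoint gene on the same chromosome (signal 92.8, summit 9544421, 195 bp upstream). Tubulins and kinesins had 3 of 35 (odds ratio 5.68, adjusted exact p = 0.0535), among them tba-2 (115.2) and tbb-1 (96.0), and passed the threshold in 2 of the 9 alternatives (adjusted exact p from 0.0174 to 0.540). Spindle and kinetochore genes with a peak numbered 3 without replicate 1 (odds ratio 3.76, adjusted exact p = 0.129) and 0 without replicate 2 (adjusted exact p = 1.00), the range over alternatives. With counts this small the intervals leave room for several-fold enrichment.

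The other groups of broadly used genes did not pass the threshold against other genes either. The vacuolar ATPase had 2 of 21 (vha-2 and vha-12, adjusted exact p = 0.110), splicing factors 3 of 51 (lsm-6 and rsp-1 highest, adjusted exact p = 0.115) and aminoacyl-tRNA synthetases 2 of 32 (ears-2 and fars-3, adjusted exact p = 0.204). The vacuolar ATPase and the splicing factors each passed with the window from 1000 bp upstream (adjusted exact p = 0.0243 and 0.0135, highest over all alternatives 0.710 and 0.708). Transcription machinery had 3 of 71 (rpb-11 and rpac-19 highest, adjusted exact p = 0.221), translation factors 2 of 38 (eif-3.C and eef-1A.1, adjusted exact p = 0.231), histones 3 of 81 (his-37 and his-67 highest, adjusted exact p = 0.253) and proteasome subunits 1 of 33 (rpn-3, adjusted exact p = 0.522). No mitochondrial ribosomal protein gene of 70 had a peak (adjusted exact p = 0.712). Set against shifted summits in place of other genes, tubulins and kinesins (adjusted one-sided permutation p = 0.0144), transcription machinery (0.0163), the vacuolar ATPase (0.0210), splicing factors (0.0277), synthetases (0.0288), translation factors (0.0360) and histones (0.0360) passed, while spindle and kinetochore genes (0.0701) and the proteasome (0.253) did not. That test compares a list with random places and not with other promoters, which as a whole held more summits than after shifting. Without replicate 1 splicing factors and histones had 1 gene each, and without replicate 2 splicing factors, transcription machinery, the vacuolar ATPase and synthetases had 1 each, as did mitochondrial ribosomal proteins, while translation factors had 3 (odds ratio 5.34).

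Of the groups tied to particular tissues, stages or large gene families, chemoreceptor genes alone passed the threshold against other genes in the main setting. Germline and oocyte genes had 2 of 60 (ego-1 and syp-4, adjusted exact p = 0.357), intestinal genes 1 of 35 (the yolk protein gene vit-2, adjusted exact p = 0.527) and synaptic genes 1 of 52 (egl-30, adjusted exact p = 0.670). Nuclear hormone receptors had 4 of 274 (nhr-47 and nhr-142 highest, adjusted exact p = 1.00), C-type lectins 1 of 240 (clec-126, adjusted exact p = 0.297) and detoxification enzymes 1 of 248 (gst-27, adjusted exact p = 0.297). F-box and MATH genes had 1 of 395 (fbxb-72, adjusted exact p = 0.0627) and were under-represented with the window from 1000 bp upstream (2 genes, 0.0312, range over alternatives 0.0312 to 0.810). Cuticle collagens (174 genes, adjusted exact p = 0.231), neuropeptides (140, adjusted exact p = 0.293), sperm genes (88, adjusted exact p = 0.522), homeobox genes (92, adjusted exact p = 0.522) and muscle genes (40, adjusted exact p = 1.00) had none. Germline and oocyte genes and nuclear hormone receptors exceeded their shifted means of 0.250 and 1.12 (adjusted one-sided permutation p = 0.0435 for each), and without replicate 1 they had 1 gene each. Also without replicate 1, detoxification enzymes had 3 genes (odds ratio 0.866 in place of 0.241), muscle 1 and intestinal and synaptic genes 0, and without replicate 2 F-box and MATH genes had 2 and cuticle collagens 1. Chemoreceptor genes were under-represented, with 4 of 1308 (srh-269 and srh-2 highest, odds ratio 0.174, adjusted exact p = 1.89e-05), and 2 without replicate 1 (odds ratio 0.102). Shifted summits gave a mean of 4.97 chemoreceptor genes (one-sided permutation p = 0.452), and against genes with an unthresholded peak the adjusted exact p was 0.985, the highest of the alternatives, the lowest being 3.39e-07. Several genes named in this paragraph share their summit with a short noncoding RNA gene. The summits of clec-126 and srh-269 were also counted for tRNA genes, that of gst-27 for the snoRNA gene Y53F4B.48 and that of syp-4 for the snRNA gene H27M09.6.

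The distribution over chromosomes was uneven. The X chromosome held 176 of the 731 nuclear peaks (24.1%, 21.1 to 27.3), above its 17.7% of the nuclear genome length (exact two-sided binomial p = 1.21e-05, adjusted exact p = 3.64e-05 over 6 chromosomes). Chromosome III was also above its length share (18.6% against 13.7%, adjusted exact p = 0.000500), and chromosome V below it (12.9% against 20.9%, adjusted exact p = 1.45e-07). The X peaks were of a different kind from the autosomal ones. On X 31 of 176 summits (17.6%) lay in promoter windows against 237 of 555 (42.7%) on the autosomes (two-sided Fisher exact p = 6.41e-10). Instead, 93 X summits (52.8%) lay within 200 bp of a tRNA gene, against 56 (10.1%) on the autosomes. Of the 276 tRNA genes on X, 105 (38.04%) had a peak, compared with 65 of 336 (19.3%) on the autosomes (odds ratio 2.56, 1.78 to 3.68, Fisher exact adjusted p = 9.94e-07). For snoRNA genes the order was the opposite, with 1 of 33 on X and 58 of 313 on the autosomes (adjusted exact p = 0.0385). Without the peaks near tRNA genes, a setting chosen after seeing the data though before this value was known, the X share turned to 14.3% of 582 peaks, below the length share (exact binomial p = 0.0297). X holds 13.7% of the nuclear protein-coding genes, and the 24.1% of all nuclear peaks was above that share too (exact binomial p = 5.50e-14). The 14.3% was not below it, and this class was not tested against it.

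Several of the strongest X peaks carried a known sequence element. Of the 100 strongest nuclear peaks 35 lay on X. A match, with at most 2 mismatches, to TCGCGCAGGGAG, the 12-letter motif of sites that recruit the dosage compensation complex to X in hermaphrodites, lay within 100 bp of 18 of the 176 X summits (10.2%, 6.57 to 15.6) and of 13 of those 35 (37.1%, 23.2 to 53.7). The peak on X at 11093937 to 11094395 held an exact match on the minus strand from 11094123 to 11094134, and the peak in an intron of Y41G9A.17 (2996914 to 2997287, signal 317) held another from 2997121 to 2997132. The intronic peak of mom-1 had a match with 1 mismatch (TCGCGCAGGGAA, 6296574 to 6296585, plus strand). Autosomal summits had a match in 3 of 555 cases (0.541%), which gave an odds ratio of 20.96 (6.10 to 72.1, Fisher exact p = 2.43e-09), and windows in the flanks of the X peaks in 3 of 176 (exact p = 0.000729 against the summits). The X peaks with the motif had a median signal of 296 and the other 158 X peaks one of 114.7. The motif was looked for after the X share was seen.

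**Figure D4:**
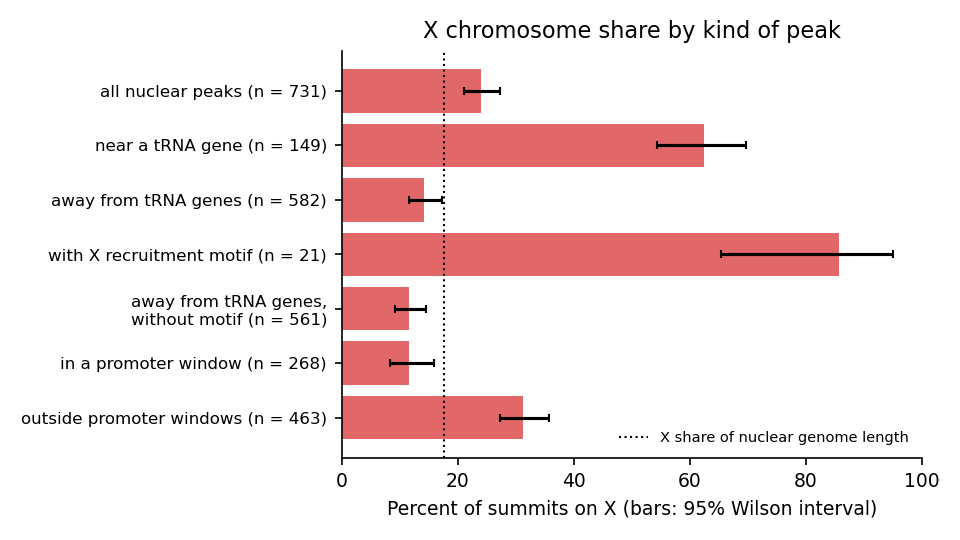
Percent of summits on X among all nuclear thresholded peaks and among classes of them, with 95% Wilson intervals, the number of peaks (n) beside each class and a dotted line at the length share of X (17.7%). Peaks near tRNA genes (62.4%) and peaks with the recruitment motif (85.7%) lie far above the line, and peaks away from tRNA genes (14.3%) below it.

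On the autosomes, 318 of 555 summits (57.3%, 53.1 to 61.3) lay in the gene-rich middle portion from 25% to 75% of the length, against an expectation of 50% (exact two-sided binomial p = 0.000671). Against the 55.7% of autosomal protein-coding genes that start there, the share did not differ detectably (exact binomial p = 0.442). With the stronger 375 peaks alone it was 55.8% (exact binomial p = 0.0708).

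Sequence words around the summits were compared with flanks centred 300 bp to the left. The 5 words of 6 letters with the lowest p among those more frequent at summits were GAGCGC, found within 50 bp of 10.5% of summits and in 1.2% of flanks, ACGCGC (11.3% and 1.60%), CGAACC (10.1% and 1.33%), GACGCA (11.2% and 1.87%) and AGACGC (11.9% and 2.27%). Their adjusted p-values from the exact McNemar test were between 3.17e-12 and 2.17e-11. The contrasts were smaller without replicate 1 for GAGCGC (7.20% and 2.27%), GACGCA (7.87% and 3.07%) and AGACGC (9.60% and 3.07%), and without replicate 2 for CGAACC (8.93% and 2.00%) and GAGCGC (9.33% and 1.60%). CGAACC and its complement belong to the internal promoter of tRNA genes. The longer word GGTTCGA lay at 35.6% of the summits near tRNA genes and at 2.58% of the others (Fisher exact adjusted p = 1.79e-26), and without the peaks near tRNA genes CGAACC no longer passed (adjusted exact p = 0.0725, lowest over the other settings 1.72e-12). GGTTCGA holds the complement of CGAACC and was chosen from the words of the same peaks. Its excess near tRNA genes therefore follows from how that class was defined and is no evidence about the tagged protein. GACGCA was rarer near tRNA genes (4.03%) than elsewhere (13.4%, adjusted exact p = 0.00238). On X alone ACGCGC and GACGCA did not pass (adjusted exact p = 0.337 and 0.503, lowest over the other settings 1.48e-16 and 2.74e-12).

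Of the words fixed in advance, CTGCGT (11.7% and 2.40%, adjusted exact p = 3.48e-10), GAGAGA (18.3% and 8.53%, adjusted exact p = 1.87e-06), CCGCCC (4.40% and 1.73%, adjusted exact p = 0.0216) and GCGGGA (4.27% and 1.73%, adjusted exact p = 0.0288) were more frequent at summits. The run TTTTTT (20.4% and 38.9%, adjusted exact p = 7.23e-12), the splice acceptor word TTTCAG (7.33% and 16.5%, adjusted exact p = 3.02e-06) and the GATA-type word TGATAA (5.33% and 9.07%, adjusted exact p = 0.0370) were less frequent. CACGTG (adjusted exact p = 0.223), TATAAA (0.0788) and TGACGT (0.748) did not pass. In total 287 of 2080 words were more frequent at summits (157 without replicate 1) and 193 less frequent. Summit windows had a mean GC content of 46.1% ± 9.56 (SD, n = 750) and flanks 36.5% ± 9.09, a difference for which the word tests were not adjusted.

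**Figure D5:**
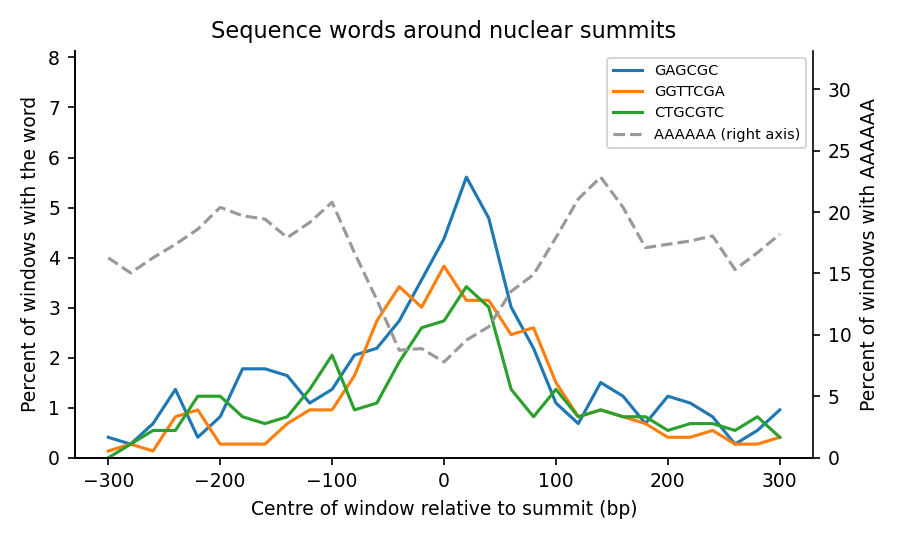
Percent of windows reaching 20 bp either side of each offset from the summit (x axis, bp) that hold GAGCGC, GGTTCGA or CTGCGTC (left axis) or AAAAAA (right axis), over the 731 nuclear summits. GAGCGC reaches 5.61% at 20 bp, while AAAAAA falls to 7.80% at the summit.

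Around the tagged gene itself, which lies on chromosome IV from 11310972 to 11312518 on the plus strand, no thresholded summit lay within 20 kb, and the nearest was 131632 bp away. As few were found for 75.1% of protein-coding genes (mean 0.329). The pooled list before thresholding had a summit in the gene body (rank 944, signal 79.96) and 25 within 20 kb, a number that 93.0% of protein-coding genes did not reach. The lowest signal in the thresholded ce11 set was 88.6, so the gene-body summit fell below the cutoff. In ce10 the thresholded set was larger, with 1083 peaks and a lowest signal of 76.1. Whether the ce10 set holds a summit near this gene was not examined, so the absence of one applies to the ce11 set only.

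The same libraries were also given in the ce10 build, where the thresholded set held 1083 peaks, 1.44 times as many as in ce11. At or above a signal of 114, the ce11 median, there were 373 in ce10 and 375 in ce11, a comparison that assumes 1 signal scale for both lists, which is not known. No coordinates were compared between the builds.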

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

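The tests of X signal over the whole chromosome, of the recruitment motif and of the coverage of the mitochondrial genome were chosen only after the results they bear on were seen, and so were the counts of abundantly transcribed gene groups by setting and against shifts. The test of tRNA genes on X was chosen after the X share was seen but before its own value was known. The tests of each replicate and of abundantly transcribed gene groups were set before their values were known; that of each replicate was left out for a time once its outcome was visible, and then restored as first written. Because the design holds 1 group, no biological explanation that it names was tested, and the tests of tRNA genes and of the motif ask only where the X peaks lie.

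The mitochondrial genome, which the nuclear comparisons leave out, held 19 thresholded peaks. No control was counted, so this number alone does not show an excess. Their median signal was 1974 against 113 for nuclear peaks, and they merged into 7 regions covering 77.1% of the 13794 bp of that genome (75.4% in replicate 1 and 72.3% in replicate 2). Signal over the whole mitochondrial genome, rather than at particular sites, is therefore a candidate explanation, since many copies of it are present per cell. Whether untagged animals or input DNA show as much was not analysed here.

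The X chromosome held 24.1% of the nuclear peaks against 17.7% of the length. More signal over all of X is argued against by the weaker peaks of the pooled list, of which 17.6% of 29249 lay on X. For replicate 2 taken alone it stays open. There X held 4821 of the 25015 nuclear peaks of the whole list, above the length share. In replicate 1 it held 5094 of 29979, below that share, and neither was tested. An excess in 1 replicate alone is argued against by the X shares of the 750 strongest nuclear peaks. These were 22.8% and 24.0% in replicates 1 and 2, each above the length share (exact binomial p = 0.000385 and 1.25e-05). The recruitment motif does not account for all of it, because 22.3% of the peaks without a match still lay on X (exact binomial p = 0.00190), although 10.2% of X summits had a match against 0.541% of autosomal ones, which leaves it as a candidate for part of the excess. Peaks near tRNA genes could account for it, since the X share of the other 582 peaks was 14.3%, below the length share. As 62.4% of the peaks near tRNA genes lie on X, leaving them out could only lower the share, though by how much was not fixed. Why tRNA genes on X had peaks more often than those on the autosomes stays open.

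Promoter peaks at ribosomal protein, chaperone and other broadly used genes may reflect nonspecific enrichment at promoters of highly transcribed genes. Of 7 groups assumed to be abundantly transcribed in young adults, 3 were over-represented (cytosolic ribosomal proteins, chaperones and oxidative phosphorylation), while translation factors, the vacuolar ATPase, cuticle collagens and muscle genes were not. At least 5 would have favoured that explanation and 2 or fewer would have argued against it. The number was 2 without replicate 1, where oxidative phosphorylation did not pass, between 1 and 4 over all settings, and 5 against shifted summits, where translation factors and the vacuolar ATPase passed too, so nonspecific enrichment cannot be told apart from binding of the tagged protein here. No RNA levels, untagged animals or other tagged proteins were analysed here. Whether a group passed also depended on its size. The vacuolar ATPase, with 2 of 21 genes, did not pass at an odds ratio of 6.36, while oxidative phosphorylation, with 4 of 48, passed at 5.52.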

How the results depend on the processing

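The alternatives without mitochondrial peaks, with 1 summit per 500 bp, without peaks near tRNA genes, with peaks chosen by 1 replicate for the correlation and with X or autosomal words alone were chosen only after seeing the data; the others were fixed before. Among the recomputed values 78 kept their direction and their side of the threshold, or for counts their size within 1.5 times, while 11 moved, 2 lost their call and 1 reversed. Of the 78, 17 could not have changed, because the strongest peaks of the pooled list are the thresholded set, results on nuclear peaks already leave out the mitochondrial ones, and fewer peaks or a shorter distance cannot raise the 0 peaks around the tagged gene. That 0 was counted in ce11 lists only, and the larger thresholded set of ce10 was not tried. The ratio of ce10 to ce11 peaks, 1.44, became 0.995 above the ce11 median signal, which assumes 1 signal scale for both lists. Without the peaks within 200 bp of a tRNA gene the X share turned to 14.3%, below the length share, because 93 of those 149 peaks lie on X. The 14.3% was not below the 13.7% of nuclear protein-coding genes that lie on X. The autosome centre share lost its call with the stronger 375 peaks (55.8%, exact binomial p = 0.0708) and against the share of genes (57.3% against 55.7%, exact binomial p = 0.442). Genes with a promoter peak fell from 334 to 163 with the stronger 375 peaks and to 157 with the narrower promoter window, as fewer summits or shorter windows must give, and with that window 5 lists in place of 9 were over-represented. Words more frequent at summits went from 287 to 113 with the stronger peaks, 145 with windows of 25 bp, 162 and 190 with words of 5 and 7 letters, 187 on the autosomes alone and 62 on X alone, settings with fewer summits, shorter windows or another number of words. With each replicate alone the ranges were 157 to 231 words, 285 to 326 genes, 7 to 8 lists, promoter shares of 34.1% to 36.4%, X shares of 22.5% to 23.7%, centre shares of 58.3% to 58.9%, divergent odds ratios of 2.25 to 3.34 and 0 peaks around the tagged gene; the low of 157 words was without replicate 1, and the cause was not tested. The overlap of the replicates ranged from 53.3% to 62.5%, rho from 0.382 to 0.569 and the promoter share, with its expectation, from 19.6% against 6.16% to 68.9% against 23.1%, all at the smallest permutation p possible (0.001 for shifts and 1e-05 for correlations). No paired analysis was possible because there is only 1 group. Depth is unknown, so how it limits the weaker peaks cannot be given.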

Other observations

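The motif sites, the classes of X peaks and the other genes described here were chosen only after the data were seen, and so was the test of tRNA genes on X, though before its own value was known.

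Among the 20 strongest nuclear peaks, 10 lay on X, and 8 of these lay outside protein-coding genes and their promoter windows. The peak on X from 14525521 to 14526097 (signal 440) lay 706 bp from nspc-17 and held the motif variant TCGCGCAGGGAC with 1 mismatch (14525898 to 14525909, minus strand). The peak from 4209107 to 4209444 (signal 317), 1290 bp from hpk-1, a gene of a nuclear protein kinase, held TCGCGAAGGGAG with 1 mismatch (4209290 to 4209301, plus strand). The peak from 1626976 to 1627323 (signal 314), 990 bp from fbxb-58, held TCGCGAAGGGAT with 2 mismatches (1627104 to 1627115, plus strand). The peaks from 9465665 to 9466002 (signal 398), 1101 bp from ZK899.6, and from 13700628 to 13701034 (signal 377), 3082 bp from the noncoding RNA gene K02D3.5, had no match. On the autosomes, the peak on chromosome V from 1151314 to 1151622 (signal 346) lay over linc-128, a long noncoding RNA gene.

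Of the 8 genes of the DREAM complex, which represses cell cycle and germline genes in somatic cells, 5 had a promoter peak, while efl-1, dpl-1 and lin-37 had none; this group was looked at because some of its members had peaks, so the count was not tested. They were lin-54, lin-53 and lin-35, as described, lin-9 (signal 119, summit 8904268 on chromosome III) and lin-52 (signal 102, summit 9824708 on chromosome III). The chromatin genes met-1, which encodes a histone methyltransferase (signal 112.4), and mrg-1 (signal 88.8) completed the 8. In the group of transcription machinery, the third gene was rpc-2 (signal 92.1, summit 5557486 on chromosome III), which encodes a subunit of RNA polymerase III, the enzyme that transcribes tRNA genes. Both subunits of the cytosolic ribosome were represented, the small one by rps-19 (signal 193), rps-1 (signal 187) and rps-28 (signal 130). These genes were not tested as groups of their own.

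A hypothesis is that the X excess is made of peaks at tRNA genes and, to a lesser extent, at recruitment sites of the dosage compensation complex. Away from tRNA genes the X share was 14.3% of 582 peaks, and away from both tRNA genes and motif matches it was 11.6% of 561 (exact binomial p = 0.000101), below the length share of 17.7%, while among those of the latter outside promoter windows it was 13.6% of 323 (exact binomial p = 0.0578). Against the 13.7% of nuclear protein-coding genes on X, 14.3% was not low, and none of these classes was tested against that share. The motif alone could explain only a part, as 10.2% of the X summits had a match. Peaks near tRNA genes and peaks with a match lie mostly on X (62.4% and 85.7%). Leaving them out could only lower the X share, so these p-values do not test the hypothesis. Without the peaks near tRNA genes no excess over the length share was left, so whether the motif adds to it cannot be told. Of the X peaks, 43 of 176 (24.4%) lay in a promoter window of no gene, near no tRNA, snoRNA or snRNA gene and without a match, and on the autosomes 216 of 555 (38.9%). The hypothesis was found and examined on the same data, and it leaves open whether the tagged protein or the open chromatin of such places brings the signal.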
